A study of Mus musculus with 8 samples.

How the data were processed

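RNA of single liver cells was measured on the 10x Chromium platform (v2 chemistry, which counts tags from the 3' ends of transcripts) in 8 mice, 1 library per mouse. The mice carried loxP-flanked Il17ra without cre (floxed) or with villin-cre, and were naive or injected with concanavalin A (ConA), with 2 mice in each of the 4 groups. The deposited files are filtered gene-barcode matrices that hold UMI counts per gene and cell barcode, made by the authors with Cell Ranger 2.1.0 on the mm10 build. The labels also list Seurat 2.3.1, whose output was not analysed here. The values of all 8 matrices were checked to be whole numbers whose sums differ between libraries. Together the files hold 53033 barcodes, 27998 genes and 98408804 UMIs. Of the gene identifiers, 27722 were found in GENCODE vM21 (build GRCm38), which gave the positions printed here.

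Cells with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, which left 44051. Doublets were scored in each library against simulated pairs of its own cells, 2 per cell, at an assumed rate of 0.8% per 1000 barcodes, and 2854 cells were removed, leaving 41197. Counts were scaled to 1500 UMIs per cell and log-transformed. Cells were clustered on 2035 genes (2000 variable genes plus cell type markers). Response gene lists, sex-linked, mitochondrial, ribosomal, hemoglobin, heat-shock and predicted genes and immunoglobulin and T cell receptor segments were left out unless they were markers. The clustering used 30 principal components, 20 nearest neighbours, edges with at least 3 shared neighbours and the Leiden method at resolution 1. It gave 41 clusters.

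Clusters were named from 16 marker sets. The score of a set was its mean log2 ratio over the median cluster with a floor of 20 CPM (counts per 1000000 UMIs). A name needed a score of at least 1 that led the next cell type by at least 1, at least 3 markers raised 2-fold, at most 30% called doublets, and among the 10 leading genes no more markers of any other type than of its own. This named 30 clusters. Named clusters are called "-like", since no protein or sorting data stand behind them. Of the 11 unnamed clusters, the largest that doublets did not lead, cluster 15, was compared by number. It was pooled with the monocyte or dendritic cell-like class for cell shares. Clusters 25, 27 and 34 and the remaining unnamed clusters entered the whole library and the share denominators but no class.

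UMI counts were summed per library over all analysed cells (whole library) and per cell class. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM factors, robust quasi-likelihood F test) in 1 fit per class, with 4 groups of 2 libraries and 4 residual degrees of freedom where all groups had enough cells. Cholangiocyte-like cells and cluster 15 were fitted with 6 libraries and 3 residual degrees of freedom. Monocyte or dendritic cell-like, neutrophil-like and plasmacytoid dendritic cell-like cells were fitted with 4 libraries and 2 residual degrees of freedom. The contrasts were ConA against naive (4 against 4 mice, averaged over genotype), villin-cre against floxed in naive mice, the same in ConA mice (2 against 2 each) and the interaction. A class was tested where every library of the contrast had at least 20 of its cells. Benjamini-Hochberg adjustment ran over all genes of a class and contrast, and genes with an adjusted p under 0.05 are called. Tests are two-sided. Adjusted p values of genes and of cell shares are from edgeR unless another tool is named, and every log2 fold change has its standard error (SE) after ±. Levels are mean CPM ± SD over the libraries of a group, without the TMM factors that the fitted log2 values include. A gene with no UMI in 1 of the groups is given as at least N-fold, against a floor of 3 counts over that group. With 1 to 3 counts the ratio of summed counts stands with its 95% counting interval. Intervals and floors cover counting error only.

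Before the data were examined, the tests, 18 gene lists, the 16 marker sets, the rule for named genes and most alternatives were fixed. Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation between genes of 0.01, log2 CPM with a prior count of 2). The adjustment ran over all lists and classes of a contrast, and each call was tested again with an estimated correlation. The power of that second test was not simulated, so a list that did not pass it is not shown to be unchanged. For list members, counts are given over all genes tested and adjusted over the list alone. Camera asks whether a list moves more than the other genes. The rule names Il17ra, Il18, Ifng, Fasl, Tnf and Tlr9 always. In each contrast it adds the 3 largest rises and 3 largest falls in the whole library, and the 2 largest rises and the largest fall in each class. These had to be called, with at least 10 UMIs per library in the higher group and no overlap of the groups. Predicted genes, receptor segments, mitochondrial, ribosomal and sex-linked genes and markers of other classes were excluded there. It also adds up to 4 members per list in the class with most calls. Members of a list named beyond this rule, and Rpl36-ps3, Gm9843, Gm42418 and the cytokines listed by source, were chosen after their values were seen.

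Cell shares were tested with edgeR on cell counts per class with all analysed cells as library size, adjusted over 12 classes. An exact permutation test of 4 against 4 libraries stands beside it, with 70 permutations and 0.0286 as the smallest p it can give. Single shares have Wilson 95% intervals. No paired analysis was possible because replicate numbers follow the order of deposition and match no animal of one group to an animal of another.

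The fits were tested on simulated data with 100 genes changed at each fold. In ConA against naive the test recovered 70% of 2-fold and 96% of 4-fold changes in the whole library, 62% and 93% in endothelial cell-like, 60% and 89% in T cell-like and 60% and 89% in Kupffer cell-like cells. In villin-cre against floxed after ConA it recovered 34% and 85% in the whole library, 35% and 89% in endothelial cell-like, 34% and 84% in T cell-like and 15% and 69% in Kupffer cell-like cells. In 50 simulated tables of 13 classes, only the Kupffer cell-like share was changed, by a log2 of -2 in ConA against naive, at a preset spread. The share test recovered it in every table, with a median estimate of -2.01. Smaller changes, other classes and the genotype contrasts were not simulated for shares.

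The alternatives were DESeq2 1.42.0 size factors and the DESeq2 test, no low-count filter, called doublets kept, a stricter cell filter (500 genes, 10% mitochondrial UMIs) and Leiden resolution 2. Each library was left out in turn, genotype contrasts were run with only the 4 libraries compared, and TMM factors over classes and the estimated correlation were tried. Chosen after the data were examined were a sex term, only cells with at least 1300 UMIs, a minimum of 0.65 times the library median (for shares, after 3 other multiples had been looked at), cluster 15 counted as Kupffer cell-like, and the data without both ConA libraries rich in cluster 8. The largest shift of the median gene between TMM and DESeq2 scaling was 0.05 on the log2 scale. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.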

Results

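Single-cell RNA was sequenced from the livers of 8 mice aged 6 weeks, 1 library per mouse. All mice carried loxP-flanked Il17ra, the gene of a subunit of the interleukin-17 (IL-17) receptor. The floxed mice had no cre, and the villin-cre mice carried a cre transgene under the villin promoter, which is active in intestinal epithelium. In each genotype 2 mice were naive and 2 had received concanavalin A (ConA), a lectin that activates T cells and injures the liver, at 25 mg/kg into a vein 90 minutes before the liver was taken. The floxed naive libraries held 14605607 and 15215011 UMIs and the villin-cre naive libraries 12358304 and 9378844. The floxed ConA libraries held 6398702 and 12602395 and the villin-cre ConA libraries 12104551 and 15745390. They gave 7679, 7887, 7573 and 4478 analysed cells from naive mice and 1648, 3848, 3472 and 4612 from ConA mice, in the same order.

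The naive and ConA libraries differed in more than the injection. Median UMIs per kept cell were 847 to 1358.5 in naive and 2449.5 to 2825 in ConA libraries. The lowest UMI count of any barcode was 506 to 718 against 1145 to 1282, and hemoglobin took 15.4 to 29.7% against 2.74 to 6.88% of UMIs. Xist and Y-linked transcripts showed replicate 1 of each naive group to be male and all other mice to be female. The mouse numbers of the naive and ConA animals come from separate series, and no label gives the processing day.

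The first question was which liver cells changed in number and expression 90 minutes after ConA. Kupffer cell-like cells, the resident macrophages of the liver, fell from 5.63% ± 2.15 (SD, n = 4) of analysed cells to 1.83% ± 0.308 (n = 4). Plasmacytoid dendritic cell-like cells, known as producers of type I interferon, fell from 1.74% ± 0.288 to 0.405% ± 0.0339. Neutrophil-like cells rose from 0.180% ± 0.0634 to 1.01% ± 0.439, and stellate cell or fibroblast-like cells from 0.754% ± 0.309 to 2.21% ± 0.230. Endothelial cell-like cells were the most abundant class, at 45.3% ± 3.33 in naive mice and between 40.4 and 57.6% in the ConA libraries (adjusted p = 0.673).

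The log2 fold changes of these shares in edgeR were -1.64 ± 0.34 for Kupffer cell-like cells (adjusted p = 0.00288) and -2.10 ± 0.28 for plasmacytoid dendritic cell-like cells (adjusted p = 3.45e-04). They were 2.49 ± 0.45 for neutrophil-like cells (adjusted p = 0.00283) and 1.57 ± 0.32 for stellate cell or fibroblast-like cells (adjusted p = 0.00288). For each of these 4 classes the groups did not overlap, and the exact permutation test gave its smallest possible p of 0.0286, or 0.0857 after adjustment over the 12 classes. The other 8 classes did not pass. T cell-like cells were at 11.8% against 10.3% (adjusted p = 0.584) and B cell-like cells at 12.3% against 11.9% (adjusted p = 0.901). NK cell or ILC1-like cells were at 2.48% against 3.54% (adjusted p = 0.142) and hepatocyte-like cells at 5.55% against 3.71% (adjusted p = 0.419). With cells of at least 1300 UMIs only, a cut above the median of 3 naive libraries, 9 classes passed, and the stellate share did not, at 0.69 (adjusted p = 0.151). With the unnamed cluster 15, which carried markers of both types, counted as Kupffer cell-like rather than as monocyte or dendritic cell-like, the Kupffer change was -0.07 ± 0.39 (adjusted p = 0.902) and that of monocyte or dendritic cell-like cells -5.01 ± 0.79 (adjusted p = 0.0023). Shares are of captured cells, not of cells in the liver.

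**Figure D1:**
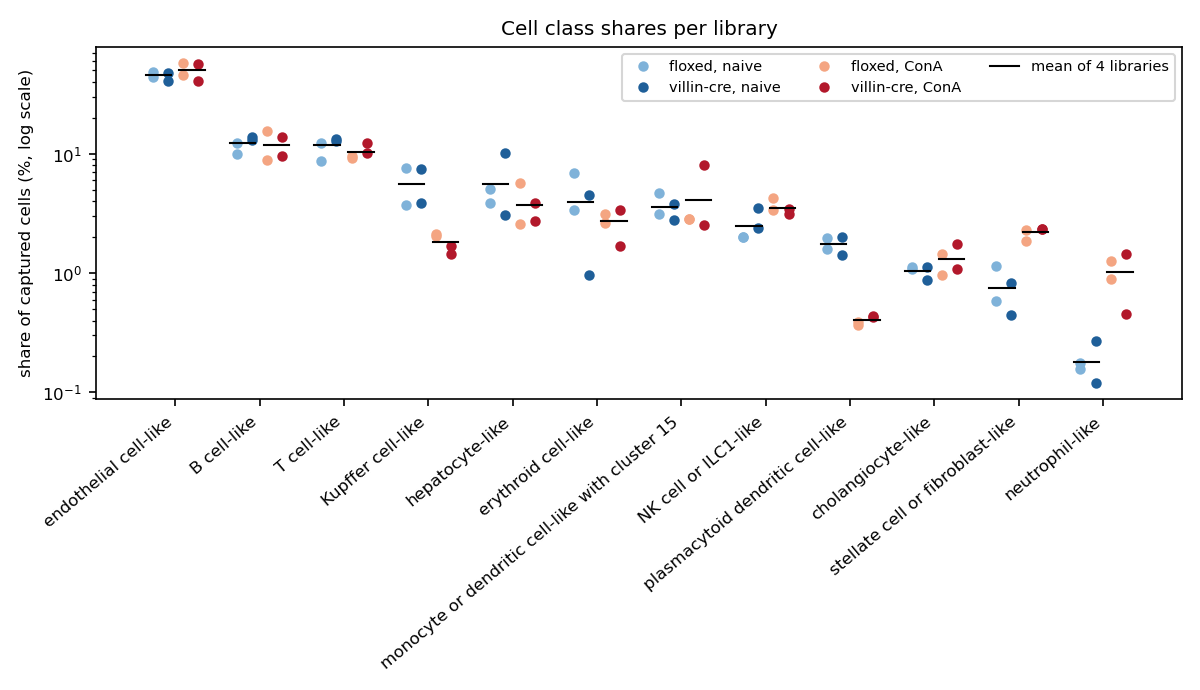
Share of analysed cells (%, log axis) in 12 cell classes, with 1 point per library coloured by group and a line at the mean of the 4 naive and of the 4 ConA libraries. Kupffer cell-like cells fell from a mean of 5.63% to 1.83% and neutrophil-like cells rose from 0.180% to 1.01%.

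Endothelial cell-like cells raised genes of inflammation after ConA. Ccl2, a chemokine that recruits monocytes, rose from 12.1 CPM to 2736 ± 1680 (SD, n = 4 mice per group; log2 8.27 ± 0.40, adjusted p = 4.09e-06). Icam1, an adhesion molecule for leukocytes, rose from 63.4 to 2459 ± 384 CPM (log2 5.81 ± 0.18, adjusted p = 1.58e-07). Olr1, a scavenger receptor, rose 2164-fold (counting interval 388 to 85500, 1 naive UMI). Its fitted log2 value was 11.43, or 12.51 without floxed naive replicate 2, 10.66 with a sex term and 8.77 with called doublets kept. Il17ra itself rose from 4.52 ± 1.67 to 38.0 ± 13.8 CPM (log2 3.66 ± 0.31, adjusted p = 4.01e-05).

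By list, all 23 measured TNF and NF-kB targets rose in endothelial cell-like cells (median log2 3.40, camera adjusted p = 4.33e-16; adjusted p = 0.147 with an estimated correlation). Of 12 members of the IL-17 list, which holds target genes shared with other inflammatory signals, 10 rose, among them Cxcl1 (log2 8.13 ± 0.31) and Ccl20 (log2 9.29 ± 0.27). The list median was 4.11 (camera adjusted p = 1.62e-07; adjusted p = 0.147 with an estimated correlation). Of 19 chemokines 14 rose, with Ccl12 at least 171-fold higher, and Ccl6 fell. Their median was 3.97, or 3.76 with genes absent in naive libraries at their bound (camera adjusted p = 1.28e-05; adjusted p = 0.283 with an estimated correlation). Of 14 coagulation and adhesion genes 8 rose, among them Plaur, the urokinase receptor (log2 7.17 ± 0.35), and Sele and Selp, the endothelial selectins (log2 4.71 and 4.49). Selplg, the P-selectin ligand, fell (list median 2.75, camera adjusted p = 5.04e-04; adjusted p = 0.283 with an estimated correlation).

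Interferon lists rose too. In endothelial cell-like cells 15 of 17 interferon gamma response genes rose and none fell (median 3.24, camera adjusted p = 1.17e-09; adjusted p = 0.285 with an estimated correlation). Of 19 type I interferon response genes 17 rose, 18 adjusted over the list alone (median 1.36, camera adjusted p = 4.72e-06; adjusted p = 0.438 with an estimated correlation). Among them were Ifi47, an interferon-induced GTPase, at log2 3.92 ± 0.31 and Zbp1, a nucleic acid sensor, at log2 2.11. Of 12 genes of MHC class I presentation 7 rose, 8 with 1 fall adjusted over the list alone, led by the peptide transporter gene Tap1 at 3.24 (camera adjusted p = 0.0314; adjusted p = 0.58 with an estimated correlation). In contrast, all 8 measured genes of MHC class II presentation fell (median -1.20, camera adjusted p = 0.00322; adjusted p = 0.438 with an estimated correlation). H2-Ab1 fell from 105 to 32.8 CPM (log2 -1.24 ± 0.20, adjusted p = 0.00137) and H2-DMb2 by log2 -1.73 ± 0.32. The call of H2-DMb1 (-1.21, adjusted p = 0.0353) ended with DESeq2 (adjusted p = 0.086) and with at least 1300 UMIs (adjusted p = 0.0857). It also ended without floxed naive replicate 2 (-0.70, adjusted p = 0.183), villin-cre naive replicate 1 (adjusted p = 0.0836) or 2 (adjusted p = 0.0873), floxed ConA replicate 1 (adjusted p = 0.0566) or 2 (adjusted p = 0.124), or villin-cre ConA replicate 2 (adjusted p = 0.0612). That of H2-DMa (-1.38) ended without floxed naive replicate 2 (adjusted p = 0.0583) or floxed ConA replicate 2 (adjusted p = 0.0666). In this class 19 called markers of other cell types were higher and 16 lower.

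Genes of sinusoidal endothelial functions did not move as a group in endothelial cell-like cells. The class lay largely in other clusters after ConA, and cluster 3, led by Rspo3, held 1782 naive and 0 ConA cells and cluster 28, with Rspo3 among its leading genes, 0 and 338, so a change of a gene in the class includes this change of clusters. Of 15, Lyve1, a hyaluronan receptor, Cd36 and Nos3 rose and Rspo3, Maf and Gata4 fell. The scavenger receptor genes Stab1 and Stab2 were at log2 0.06 and 0.00 (list median 0.06, mean -0.05, camera adjusted p = 0.977). Of 12 cell cycle genes 5 rose, 6 adjusted over the list alone (median 0.50, camera adjusted p = 0.00804; adjusted p = 0.396 with an estimated correlation). Among them Pcna was at log2 1.10 ± 0.12. With cells of at least 1300 UMIs the direction turned for Mki67 (0.90 against -0.08), Ube2c (0.82 against -0.27) and Cdk1 (0.57 against -0.12). Ccl21a, a chemokine of lymphatic endothelium, was lower in this class (log2 -5.65 ± 1.39, adjusted p = 0.0301). The call ended without floxed ConA replicate 1 (-5.91, adjusted p = 0.0968), floxed ConA replicate 2 (-5.35, adjusted p = 0.118), villin-cre ConA replicate 1 (-6.05, adjusted p = 0.109) or villin-cre ConA replicate 2 (-5.26, adjusted p = 0.122). Without floxed naive replicate 2 or villin-cre naive replicate 2 it was -4.49 or -4.40. Within the class Ccl21a led cluster 17, which held 567 naive and 12 ConA cells. Ccl21a also led the unnamed cluster 27, with 0 naive and 365 ConA cells, which is not part of the class. A fall of Ccl21a in the class therefore cannot be told apart from which of these clusters was named.

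Kupffer cell-like cells raised cytokine genes. Il1b, the gene of the pyrogenic cytokine interleukin-1 beta, rose from 184 to 3694 ± 864 CPM (SD, n = 4 per group; log2 4.57 ± 0.31, adjusted p = 1.07e-04), and Tnf, the gene of tumour necrosis factor, from 8.33 to 387 ± 53.7 CPM (log2 5.67 ± 0.23, adjusted p = 4.43e-13). Il18, the gene of the inflammasome-processed cytokine interleukin-18, rose from 87.9 ± 21.6 to 161 ± 65.7 CPM (log2 1.05 ± 0.22, adjusted p = 0.00118). Il17ra rose from 41.2 to 152 CPM (log2 2.22 ± 0.21, adjusted p = 1.08e-07). Cxcl3, a neutrophil chemoattractant, was at least 178-fold higher.

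In the Kupffer cell-like class all 21 TNF and NF-kB targets (median 3.75, camera adjusted p = 8.91e-18) and all 7 IL-17 list genes (median 5.52, camera adjusted p = 1.34e-07) rose, each with an adjusted p = 0.0843 with an estimated correlation. Of 10 genes of the IL-18 and inflammasome list 6 rose, among them Nlrp3, the inflammasome sensor (log2 3.66 ± 0.17), and Il1rn, the interleukin-1 receptor antagonist (log2 5.52 ± 0.17). Pycard, the inflammasome adaptor, fell by 1.08 on the log2 scale (list median 1.85, camera adjusted p = 0.00411; adjusted p = 0.172 with an estimated correlation). All 7 genes of MHC class II presentation fell (median -0.88, camera adjusted p = 1.48e-04; adjusted p = 0.228 with an estimated correlation). Of 11 sinusoidal endothelial genes 9 rose, for example Clec4g and Fcgr2b (log2 1.87), and the transcription factor gene Maf fell (median 1.45, camera adjusted p = 0.00281; adjusted p = 0.283 with an estimated correlation). In this class 16 called markers of other cell types were higher and 7 lower, and endothelial markers stood at 10.1 to 18.8% of their endothelial level in the ConA libraries.

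T cell-like cells switched on cytokine genes. Ifng, the gene of interferon gamma, rose from 50.2 ± 18.1 to 1820 ± 621 CPM (SD, n = 4 per group; log2 5.55 ± 0.14, adjusted p = 4.61e-20), and Il2, the gene of a T cell growth factor, from 9.30 to 1126 ± 488 CPM (log2 7.25 ± 0.19, adjusted p = 1.92e-16; 6.56 with cells of at least 1300 UMIs). Ccl1, a chemokine gene of activated T cells, rose 1246-fold (counting interval 426 to 6043, 3 naive UMIs), with a fitted log2 value of 10.37, or 11.52 without villin-cre naive replicate 2 and 9.73 with a sex term. NK cell or ILC1-like cells raised Ifng from 80.5 to 1476 ± 518 CPM (log2 4.29 ± 0.33, adjusted p = 6.97e-05), in a class that held T cell markers at 24.9 to 51.9% of their T cell-like level in the ConA libraries. Fasl, the gene of a death ligand of cytotoxic lymphocytes, did not pass, at log2 0.23 ± 0.23 in T cell-like (adjusted p = 0.398) and 0.46 ± 0.24 in NK cell or ILC1-like cells (adjusted p = 0.160). With cells of at least 1300 UMIs it passed in the T cell-like class at 1.45 (adjusted p = 0.0191).

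Of 15 lymphocyte activation genes in T cell-like cells 14 rose and none fell (median 2.44, camera adjusted p = 1.18e-06; adjusted p = 0.0843 with an estimated correlation). Among 15 lymphocyte effector genes 9 rose and 4 fell (median 3.45, camera adjusted p = 0.0244; adjusted p = 0.446 with an estimated correlation). Those that fell were Klrk1, an activating receptor (log2 -2.51), Ltb, a lymphotoxin subunit (-1.47), Tnfsf10, the death ligand TRAIL (-1.05), and Nkg7, a cytotoxic granule protein (-0.64). Of 20 immediate-early genes 12 rose and 4 fell, 13 and 4 adjusted over the list alone (median 1.51, camera adjusted p = 0.00123; adjusted p = 0.285 with an estimated correlation). Among them were Nr4a1, a reporter of antigen receptor signalling, at log2 5.55 ± 0.39 and Klf2, a quiescence factor, at -0.92. Of 13 cell death genes 8 rose, among them the death receptor gene Fas (log2 3.27 ± 0.44), the pro-death Bcl2l11 (2.46) and the survival genes Birc3 (2.31) and Mcl1 (1.09). Casp8 and Bbc3 fell (list median 1.09, camera adjusted p = 0.0276; adjusted p = 0.350 with an estimated correlation).

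In other lists of the T cell-like class members moved in opposite directions. Of 8 heat shock genes 5 rose, such as Hsp90aa1 (log2 1.94 ± 0.11) and Hspd1 (1.88), and Hspa1a and Hspa1b fell (median 1.42, camera adjusted p = 0.132). Hspa1b was at log2 -2.55 ± 0.28, or -3.22 without floxed ConA replicate 2 and -1.67 with cells of at least 1300 UMIs. The call of Hspa1a (-2.37) ended with a sex term (adjusted p = 0.084) and with at least 1300 UMIs (-1.57, adjusted p = 0.0838). It also ended without floxed naive replicate 1 (adjusted p = 0.066) or 2 (adjusted p = 0.0621), villin-cre naive replicate 1 (adjusted p = 0.057), or floxed ConA replicate 1 (adjusted p = 0.0727) or 2 (adjusted p = 0.0982), and the value was -2.96 without villin-cre ConA replicate 1. Of 17 interferon gamma response genes 14 rose and 3 fell, among them Psmb8 and Psmb9 (median 1.74, camera adjusted p = 0.00143; adjusted p = 0.367 with an estimated correlation). Of 12 genes of MHC class I presentation 4 rose and 5 fell, 5 and 5 adjusted over the list alone (median -0.14, camera adjusted p = 0.386). The immunoproteasome subunit gene Psmb8 fell from 772 to 185 CPM (log2 -1.67 ± 0.12). Of 12 chemokines 9 rose and Ccl5 and Ccl6 fell (median 6.43, or 5.21 with genes absent in naive libraries at their bound; camera adjusted p = 2.17e-04; adjusted p = 0.32 with an estimated correlation). In NK cell or ILC1-like cells all 9 measured chemokines rose (median 3.55, camera adjusted p = 8.7e-08; adjusted p = 0.195 with an estimated correlation), and none of 7 type I interferon response genes was called by edgeR (camera adjusted p = 0.242).

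B cell-like cells raised Myc, a growth regulator, from 94.7 to 1049 CPM (log2 3.56 ± 0.29, n = 4 per group), and Irf1, an interferon-induced transcription factor, from 30.8 to 718 CPM (log2 4.61 ± 0.19). Tlr7, an endosomal receptor for RNA, rose from 7.02 to 51.3 CPM (log2 2.93 ± 0.29, adjusted p = 3.68e-11; 2.13 with cells of at least 1300 UMIs). In this class 5 of 12 endosomal TLR signalling genes rose and 2 fell, 6 and 2 adjusted over the list alone (median 0.39, camera adjusted p = 0.290). Il17ra fell here, from 55.2 ± 1.59 to 21.6 ± 5.08 CPM (log2 -1.29 ± 0.22, adjusted p = 4.32e-06). Of 9 MHC class II genes H2-DMb1 rose and Ctss, Ciita, H2-DMa and H2-DMb2 fell, with a median of 0.08 and a mean of -0.16 (camera adjusted p = 0.623).

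Hepatocyte-like cells raised serum amyloid and chemokine genes. Saa2, an acute phase gene, rose from 51.0 to 2221 CPM (log2 5.42 ± 0.48, adjusted p = 0.00167, n = 4 per group) and Saa3 by log2 5.77 ± 0.40 (adjusted p = 4.66e-05). Of 16 acute phase genes 6 rose, 9 adjusted over the list alone (median 1.25, camera adjusted p = 1.17e-09; adjusted p = 0.278 with an estimated correlation). Cxcl10, an interferon-induced chemokine, rose from 3.90 to 1188 CPM (log2 8.40 ± 0.47), or by 9.16 without floxed naive replicate 1 and 7.76 without villin-cre naive replicate 1. In stellate cell or fibroblast-like cells all 21 TNF and NF-kB targets (camera adjusted p = 5.5e-24; adjusted p = 0.101 with an estimated correlation) and all 6 IL-17 list genes (median 6.07, camera adjusted p = 1.88e-09; adjusted p = 0.126 with an estimated correlation) rose. Ch25h, the gene of a cholesterol hydroxylase, was at least 45.3-fold higher. Of 14 sinusoidal endothelial genes 5 fell there, 8 adjusted over the list alone (median -1.24, camera adjusted p = 2.69e-06; adjusted p = 0.283 with an estimated correlation), together with 5 called markers of other cell types. Erythroid cell-like cells also showed 18 of 20 TNF and NF-kB targets higher, in a class that held endothelial markers at 34.3 to 61.3% of their endothelial level in the ConA libraries.

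In the whole library Csf3, the gene of the granulocyte growth factor G-CSF, was at least 453-fold and Cxcl3 at least 222-fold higher. The fitted log2 value of Csf3 was 11.49, or 10.89 without villin-cre ConA replicate 1. Ifng rose from 8.05 ± 2.57 to 230 ± 92.4 CPM (log2 5.06 ± 0.13, adjusted p = 6.17e-06, n = 4 per group), Tnf from 5.27 to 104 ± 47.0 CPM (log2 4.61 ± 0.43, adjusted p = 2.43e-04) and Il17ra from 23.1 ± 1.49 to 39.1 ± 5.94 CPM (log2 1.02 ± 0.14, adjusted p = 0.00124). Il18 did not pass, at 14.1 and 12.9 CPM before TMM scaling and a fitted log2 value of 0.13 ± 0.27 (adjusted p = 0.714). Tlr9, the endosomal receptor for unmethylated CpG DNA, had 5 UMIs in the naive and 4 in the ConA libraries, under the filter in every class, so that no change was detectable at this depth. The largest falls were Elovl3 (log2 -7.71), Mup7 (-6.34) and Cyp2d9 (-4.31), hepatocyte genes that were high in the male naive libraries. With a sex term the changes of Mup7 and Elovl3 shrank to -1.98 (adjusted p = 0.0561) and -2.18 (adjusted p = 0.067) and that of Cyp2d9 to -1.78. Without floxed naive replicate 1 (male) the values were -3.53 (adjusted p = 0.104) for Mup7, -5.39 (adjusted p = 0.135) for Elovl3 and -3.22 (adjusted p = 0.0512) for Cyp2d9. Without villin-cre naive replicate 1 (male) they were -4.62 (adjusted p = 0.0878), -4.14 (adjusted p = 0.372) and -2.86. Leaving out single ConA libraries also ended calls of these 3 genes, with adjusted p up to 0.179.

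In the whole library all 24 TNF and NF-kB targets rose (median 3.72, camera adjusted p = 1.44e-15; adjusted p = 0.18 with an estimated correlation). So did 13 of 15 IL-17 list genes (median 5.10, camera adjusted p = 3.07e-08; adjusted p = 0.143 with an estimated correlation). Of the type I interferon genes 14 of 21 rose, 15 adjusted over the list alone (median 1.20, camera adjusted p = 7.68e-05; adjusted p = 0.471 with an estimated correlation). Of 18 interferon gamma response genes 15 rose and 2 fell (median 3.21, camera adjusted p = 1.99e-07; adjusted p = 0.301 with an estimated correlation). Of 18 effector genes 11 rose and 2 fell (median 1.86, camera adjusted p = 0.00112; adjusted p = 0.261 with an estimated correlation). Among 12 endosomal TLR genes Myd88 and Traf6, shared adaptors of several receptors, rose by log2 2.19 and 1.41. Unc93b1, a chaperone of these receptors, fell by 0.49, and the other 9 did not pass (list median 0.10, camera adjusted p = 0.448). Of 13 IL-18 and inflammasome genes 6 rose and Pycard fell, 8 and 3 adjusted over the list alone (median 0.57, camera adjusted p = 0.0457; adjusted p = 0.446 with an estimated correlation).

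**Figure D2:**
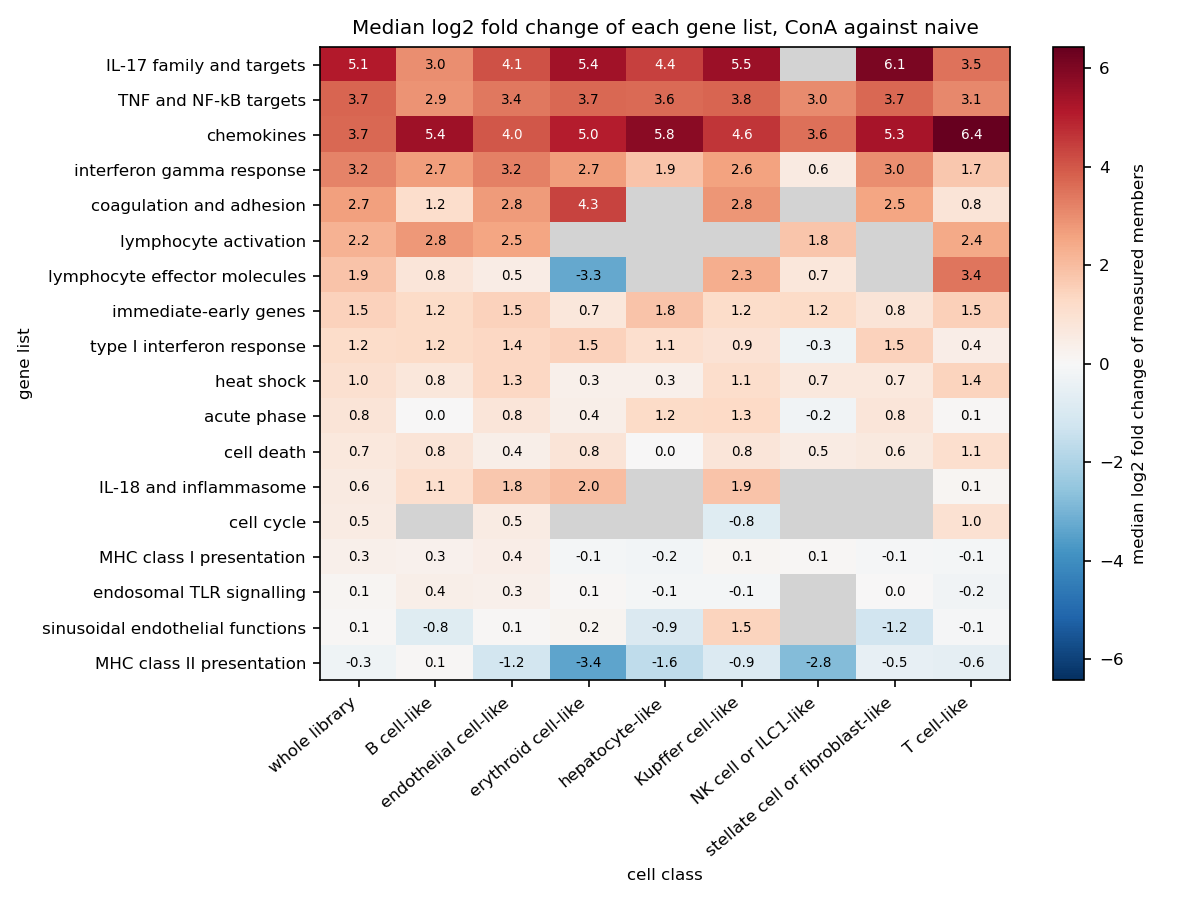
Median fitted log2 fold change, ConA against naive, of 18 gene lists (vertical) in the whole library and 8 cell classes (horizontal), coloured by value and grey where fewer than 5 members were measured. TNF and NF-kB targets are positive in every column, with 2.89 in B cell-like and 3.75 in Kupffer cell-like cells, and MHC class II genes are at -1.20 in endothelial cell-like cells.

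In all, edgeR called 3429 genes higher and 3073 lower after ConA among 13857 in the whole library. By class it called 2688 higher and 2341 lower of 11086 in endothelial cell-like, 2302 and 2246 of 7118 in T cell-like, and 1775 and 1647 of 6925 in B cell-like cells. The numbers were 898 and 642 of 4299 in Kupffer cell-like, 600 and 664 of 3718 in erythroid cell-like, and 453 and 296 of 2917 in NK cell or ILC1-like cells. They were 324 and 122 of 4212 in stellate cell or fibroblast-like and 182 and 121 of 4512 in hepatocyte-like cells. The erythroid cell-like clusters of naive and ConA libraries carried markers of different other cell types, and the counts of that class include this. Camera called 97 of 143 lists tested over classes, 87 of them up, and 0 with an estimated correlation, where the lowest adjusted p was 0.0843. With a sex term the whole-library count was 4310 in place of 6502. The hepatocyte-like count of 303 was 165 without villin-cre naive replicate 1 and 194 without floxed ConA replicate 2, and the erythroid count of 1264 was 767 without villin-cre naive replicate 1.

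The second comparison asked whether the loss of Il17ra in intestinal epithelium was accompanied by another state of the uninjected liver. In the monocyte or dendritic cell-like class Chil3, a gene of classical monocytes, was lower in villin-cre mice, at 141 and 107 CPM against 465 and 296 in floxed mice (log2 -1.63 ± 0.26, adjusted p = 0.0160, n = 2 mice per group). In T cell-like cells Ifng was at 51.4 and 75.1 CPM in villin-cre against 34.6 and 39.6 in floxed mice, a difference that did not pass (log2 0.71 ± 0.21, adjusted p = 1). Il17ra was at log2 -0.03 ± 0.20 in the whole library. Il18 in Kupffer cell-like cells was at log2 0.21 ± 0.29. No share of the 12 classes passed in edgeR (lowest adjusted p = 0.917).

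Across 12 fits, edgeR called genes in 2 classes of naive mice. Besides Chil3 there were 3 in plasmacytoid dendritic cell-like cells, among them the predicted genes Gm9843 (log2 1.25 ± 0.25) and Gm42418 (log2 -1.06 ± 0.21), each with adjusted p = 0.00234. In the whole library edgeR called 0 genes (151 at an unadjusted p under 0.05, 0 by DESeq2). Likewise edgeR called 0 genes in B cell-like (229 unadjusted), endothelial cell-like (82), erythroid cell-like (102), hepatocyte-like (67) and Kupffer cell-like cells (80), with 0 by DESeq2 in each. It also called 0 in stellate cell or fibroblast-like (294), cholangiocyte-like (227) and T cell-like cells (236), with 0 by DESeq2 in each, and 0 in NK cell or ILC1-like cells (134 unadjusted, 1 by DESeq2). The Chil3 call ended with DESeq2 (adjusted p = 0.529), at Leiden resolution 2 (adjusted p = 0.162), with at least 1300 UMIs (adjusted p = 0.855) and without floxed naive replicate 1 (-1.27, adjusted p = 0.0697). DESeq2 called 0 genes in either class. Without villin-cre naive replicate 1 the counts of these classes were 67 and 22, and without floxed naive replicate 2 the first was 21. Each naive group held 1 male and 1 female, and with a sex term the counts were 29 in monocyte or dendritic cell-like, 0 in plasmacytoid dendritic cell-like, 5 in T cell-like and 1 in NK cell or ILC1-like cells.

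Of 177 list tests in naive mice camera called 13, 9 of them up, and 0 with an estimated correlation (lowest adjusted p = 0.978). The 13 became 33 without villin-cre naive replicate 1, 25 without floxed naive replicate 2 and 23 without floxed naive replicate 1. One of them was the lymphocyte effector list in the whole library (18 members, median 0.39, camera adjusted p = 4.59e-05; adjusted p = 0.978 with an estimated correlation), with 0 single genes called by edgeR and a median of 0.20 without villin-cre naive replicate 2. The MHC class II list had a positive median in Kupffer cell-like (0.28, camera adjusted p = 0.00555) and monocyte or dendritic cell-like cells (0.56, camera adjusted p = 0.0196, 4 of 9 adjusted over the list alone). It had a negative one in hepatocyte-like cells (-0.77, camera adjusted p = 0.00858). None of its genes was called over all genes in these 3 classes, and the adjusted p was 0.978 in each with an estimated correlation. Without villin-cre naive replicate 2 the last 2 medians were 0.33 and -0.19, and without villin-cre naive replicate 1 the hepatocyte-like median was -1.67.

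The third comparison asked whether livers of villin-cre and floxed mice differed 90 minutes after ConA. Ifng in T cell-like cells was higher in villin-cre mice, at 2239 and 2460 CPM (2411 and 2828 UMIs) against 1218 and 1364 CPM (521 and 1103 UMIs) in floxed mice, a 1.84-fold difference (log2 0.88 ± 0.15, adjusted p = 0.0244, n = 2 mice per group). In NK cell or ILC1-like cells Ifng was at 1802 against 1150 CPM (log2 0.63 ± 0.35, adjusted p = 0.998), and in the whole library at 309 against 152 CPM (log2 1.06 ± 0.16, adjusted p = 0.999; DESeq2 adjusted p = 0.0392). Il18 in Kupffer cell-like cells was at 198 CPM in villin-cre and 124 in floxed mice, which did not pass (log2 0.65 ± 0.33, adjusted p = 0.898). Tnf in the whole library was at log2 0.15 ± 0.50.

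The T cell-like Ifng call rested on few mice. It ended without floxed ConA replicate 1 (log2 0.80, adjusted p = 0.374), floxed naive replicate 1 (0.85, adjusted p = 0.107) or floxed naive replicate 2 (0.89, adjusted p = 0.0625), with DESeq2 (0.88, adjusted p = 0.131), with the stricter cell filter (0.79, adjusted p = 0.0536) and with at least 1300 UMIs (0.83, adjusted p = 0.335). Without floxed ConA replicate 2 the NK cell or ILC1-like difference passed (1.33, adjusted p = 0.039).

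**Figure D3:**
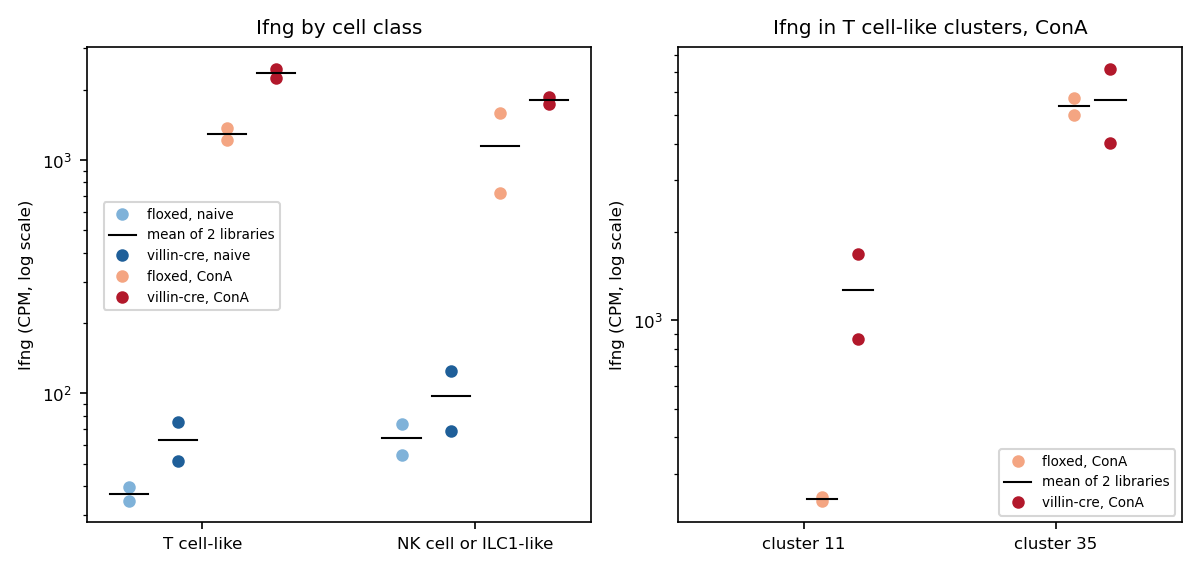
Left, Ifng level (CPM, log axis) per library in T cell-like and NK cell or ILC1-like cells of the 4 groups; right, the same in T cell-like clusters 11 and 35 of the ConA libraries, with a point per library and a line at the mean of 2 libraries. After ConA the T cell-like class lies at 1218 and 1364 CPM in floxed and at 2239 and 2460 CPM in villin-cre mice.

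Other genes called after ConA were Rpl36-ps3, a processed pseudogene, lower in B cell-like cells of villin-cre mice (log2 -1.30 ± 0.24, adjusted p = 0.0210), and Ccl2 in neutrophil-like cells (log2 4.34 ± 0.61, adjusted p = 0.0140). The Rpl36-ps3 call ended with DESeq2 and with cells of at least 1300 UMIs. The Ccl2 UMIs were 1 and 5 in floxed against 140 and 41 in villin-cre libraries, of which 82 and 38 came from single cells, and the value was 3.73 without floxed ConA replicate 1 and 5.76 without floxed ConA replicate 2. By edgeR 0 genes were called in the whole library (422 at an unadjusted p under 0.05, 1 by DESeq2). It called 0 in endothelial cell-like (446 unadjusted), erythroid cell-like (113), hepatocyte-like (95), Kupffer cell-like (210), NK cell or ILC1-like (141), stellate cell or fibroblast-like cells (231) and cluster 15 (234), with 0 by DESeq2 in each. Without villin-cre ConA replicate 2 the endothelial count was 394. Without floxed ConA replicate 2 the counts were 46 in T cell-like, 34 in erythroid cell-like, 25 in B cell-like and 61 in neutrophil-like cells and 42 in cluster 15. Without villin-cre ConA replicate 2 that of stellate cell or fibroblast-like cells was 42. No class share passed in edgeR (lowest adjusted p = 0.865).

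Of 172 list tests camera called 34 after ConA, 23 of them up in villin-cre mice, and 0 with an estimated correlation (lowest adjusted p = 0.837). In endothelial cell-like cells all 12 cell cycle genes had positive values, with Mki67 at 0.78 and Stmn1 at 1.01. None was called over all genes, and 7 passed adjusted over the list alone (median 0.77, camera adjusted p = 1.98e-09; adjusted p = 0.837 with an estimated correlation). In T cell-like cells the effector list had a median of 0.38 (1 of 15 called, 3 adjusted over the list alone, camera adjusted p = 0.0208; adjusted p = 0.853 with an estimated correlation). In the whole library the interferon gamma response had a median of 0.32 over 18 genes, all of them positive (camera adjusted p = 2.59e-04; adjusted p = 0.853 with an estimated correlation). IL-17 list genes (median 0.71, camera adjusted p = 2.43e-04) and chemokines (median 0.52, camera adjusted p = 0.00121) had positive medians in endothelial cell-like cells. None of their 12 and 19 genes was called over all genes, and 1 of the first list passed adjusted over the list alone (adjusted p = 0.837 and 0.853 with an estimated correlation). Cluster 8 of this class, led by Ccl2 and Cxcl10, took 26.7% of the analysed cells of villin-cre ConA replicate 1 and 0.932% of replicate 2, against 12.7 and 2.05% in the floxed ConA libraries. The medians of the IL-17 list and of chemokines were 0.28 and 0.17 without floxed ConA replicate 1, 0.50 and 0.31 without villin-cre ConA replicate 1, and 1.20 and 0.84 without floxed ConA replicate 2. Sinusoidal endothelial genes (median -0.95, camera adjusted p = 1.05e-09, 1 of 14 lower adjusted over the list alone) and MHC class I genes (median -0.60, camera adjusted p = 2.98e-05, 5 of 11 lower adjusted over the list alone) had negative medians in stellate cell or fibroblast-like cells. None was called over all genes, and the adjusted p was 0.837 for each with an estimated correlation. Endothelial markers in that class stood at 23.4 and 24.1% of their endothelial level in the floxed and 9.65 and 16.7% in the villin-cre ConA libraries, which goes the same way. The sinusoidal median was -0.55 without villin-cre ConA replicate 1 and -2.01 without replicate 2, and that of MHC class I was -0.39 without floxed ConA replicate 2. The effector median in T cell-like cells was 0.97 without floxed ConA replicate 2, 0.61 without villin-cre ConA replicate 1 and 0.04 without villin-cre ConA replicate 2. The whole-library interferon gamma median was 0.05 without floxed ConA replicate 1 and 0.59 without floxed ConA replicate 2.

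The interaction asked whether the response to ConA differed between genotypes. For Ifng in T cell-like cells it was log2 0.17 ± 0.26 (adjusted p = 0.992, n = 2 mice in each of 4 groups), so the higher level in villin-cre mice was not shown to be a stronger response. The gene called was Rpl36-ps3 in B cell-like cells (log2 -2.07 ± 0.34, adjusted p = 0.00167), at 53.0 and 53.7 CPM in floxed naive, 86.3 and 101 in villin-cre naive, 143 and 96.3 in floxed ConA and 49.8 and 43.1 in villin-cre ConA mice. In endothelial cell-like cells IL-17 list genes (median 0.77, camera adjusted p = 4.25e-04), chemokines (median 0.69, camera adjusted p = 6.57e-04) and MHC class II genes (median 1.01, camera adjusted p = 0.00294) had positive interactions, each with an adjusted p = 1 with an estimated correlation. Without floxed naive replicate 2 these medians were 0.32, 0.14 and 0.54. The IL-17 list median was 0.50 without floxed ConA replicate 1, 0.49 without villin-cre ConA replicate 1, 1.58 without floxed ConA replicate 2 and 1.41 without villin-cre naive replicate 2.

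By edgeR 0 genes had an interaction in the whole library (267 at an unadjusted p under 0.05, 0 by DESeq2). There were 0 in endothelial cell-like (251 unadjusted), erythroid cell-like (135), hepatocyte-like (123), Kupffer cell-like (186), stellate cell or fibroblast-like (212) and T cell-like cells (331), with 0 by DESeq2 in each, and 0 in NK cell or ILC1-like cells (123 unadjusted, 1 by DESeq2). In B cell-like cells DESeq2 called 0, and edgeR called 17 without floxed ConA replicate 2 and 0 without villin-cre naive replicate 2. Without floxed ConA replicate 2 the counts were 19 in T cell-like and 27 in erythroid cell-like cells. Camera called 16 of 143 lists, 15 of them up, and 0 with an estimated correlation (lowest adjusted p = 1). Without floxed naive replicate 1 it called 35 and without floxed naive replicate 2 it called 7. Without villin-cre naive replicate 2 or villin-cre ConA replicate 2 it called 26 each, and without villin-cre ConA replicate 1 it called 10. No class share passed in edgeR (lowest adjusted p = 0.834).

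The genes that carry the comparisons are identified as follows on GRCm38. Ifng is ENSMUSG00000055170 on chromosome 10, from 118441046 to 118445892. Il17ra is ENSMUSG00000002897 on chromosome 6, from 120463247 to 120487559. Il18 is ENSMUSG00000039217 on chromosome 9, from 50554827 to 50581840. Tnf is ENSMUSG00000024401 on chromosome 17, from 35199381 to 35202007. Fasl is ENSMUSG00000000817 on chromosome 1, from 161780689 to 161788495. Ccl2 is ENSMUSG00000035385 on chromosome 11, from 82035571 to 82037453. Csf3 is ENSMUSG00000038067 on chromosome 11, from 98701263 to 98703629. Icam1 is ENSMUSG00000037405 on chromosome 9, from 21015985 to 21028817. Il1b is ENSMUSG00000027398 on chromosome 2, from 129364570 to 129371139. Il2 is ENSMUSG00000027720 on chromosome 3, from 37120523 to 37125959. Chil3 is ENSMUSG00000040809 on chromosome 3, from 106147554 to 106167564. Rpl36-ps3 is ENSMUSG00000066629 on chromosome 12, from 12912022 to 12912336.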

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

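Among the tests in this part, those of NK cell RNA in the T cell-like class, of the gap in lowest UMIs per barcode, of a minimum relative to the library median and of cluster 15 were chosen after the result was seen. For ConA against naive, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many calls in each fit without a genotype term. Every other split put naive and ConA libraries on both sides, so their difference widened the spread within each side. Few gene calls were thus fixed in advance there, and the splits cannot exclude chance as the source of the gene counts. The real split and the highest other called 7277 and 0 genes in the whole library, 3449 and 0 in B cell-like, 5456 and 0 in endothelial cell-like, 1382 and 40 in erythroid cell-like, and 385 and 1 in hepatocyte-like cells. They called 1603 and 0 in Kupffer cell-like, 806 and 1 in NK cell or ILC1-like, 501 and 0 in stellate cell or fibroblast-like and 4598 and 0 in T cell-like cells. For cell class shares they called 4 and 0 classes. For gene lists they called 98 and 82. The 16 other splits with 3 naive libraries on one side called 62 to 82 lists and the 18 with 2 called 1 to 36, so a high count of lists does not need the real split. No label gives a processing day, so a difference between days was not tested.

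The first pattern is that most TNF and NF-kB targets were higher after ConA in the 8 classes tested, such as 19 of 19 in B cell-like and in T cell-like, 15 of 15 in hepatocyte-like, 18 of 20 in erythroid cell-like and 13 of 14 in NK cell or ILC1-like cells. As lists they did not pass with an estimated correlation (lowest adjusted p = 0.0843). Free RNA and doublets from other classes were tested as a source: the observed level was set against the level that other classes' markers allow in the same libraries. The median ratio was 4.87 in B cell-like, 4.01 in hepatocyte-like, 4.09 in Kupffer cell-like, 4.22 in stellate cell or fibroblast-like and 6.55 in T cell-like cells, above 2 in every ConA library, which argues against free RNA as the whole source of the list median there. In the same order, single genes above 2 in every library were 13 of 19, 8 of 15, 15 of 21, 17 of 21 and 10 of 19. The allowed level rests on median marker levels, which were 0% for some source classes, so it can be too low. In erythroid cell-like cells the ratio was 1.01 (0.677 to 1.12 over the ConA libraries), with 0 of 18 genes above 2 in every library. The observed level there was thus about the level that other classes' markers allow, and no response of the cells beyond it was shown. In NK cell or ILC1-like cells (2.96, lowest library 1.97) free RNA and doublets cannot be told apart from a response. The ratio did not clear 2 in all 4 ConA libraries there. A response to ConA in the 5 other classes is a hypothesis, found and tested on the same data.

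The second pattern is the higher Ifng level in T cell-like cells of villin-cre mice after ConA. RNA of NK cells in that class would need an NK level above that of the class, and the highest ratio of NK to T cell-like Ifng in the villin-cre ConA libraries was 0.7755, which argues against it. Another mix of T cell-like clusters was tested within the largest one, cluster 11, where Ifng was at 1677 and 867 CPM in villin-cre against 250 and 243 CPM in floxed mice (log2 2.37), which argues against a mix at the level of clusters, while in cluster 35 the log2 ratio was 0.06. Open remain a mix of cell states finer than clusters and a difference between the 2 mice of each group that has nothing to do with genotype. That loss of Il17ra in the gut may raise Ifng in liver T cells is a hypothesis for which these 4 mice are too few.

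The third pattern is the lower share of Kupffer cell-like cells after ConA. The same minimum of 1300 UMIs in all libraries gave a log2 change of -2.44 in place of -1.64. It lies above the median of 3 naive libraries, where it keeps classes with many UMIs. The gap in lowest UMIs per barcode therefore cannot be told apart from a change in the tissue by it, because the cut itself raises the naive share. The label of that test was set to this after its value was seen. A minimum of 0.65 times the library median, above the lowest barcode of every file (0.529 to 0.623 in naive and 0.405 to 0.523 in ConA libraries), gave -1.73 (adjusted p = 0.0034). That argues against a lower limit that differs relative to depth, though other such minima had been looked at before it. ConA Kupffer cells under the lowest count of their file are in no table and stay open. Kupffer cells present but not recognised were tested by their 10 markers in the whole library, which all fell, with a median of -1.45 (from -2.15 to -1.09). That argues against cells that kept their markers, but the test took this for granted, and cells that lost them would show the same fall. Cluster 15, unnamed with scores of 1.997 for monocytes or dendritic cells and 1.925 for Kupffer cells, held 540 cells of ConA and 92 of naive libraries. Counted as Kupffer cells it left a log2 change of -0.070 ± 0.39 (5.96% against 5.77%), and counted as monocytes or dendritic cells it left their share at 0.12 ± 0.38. In its ConA cells the median Kupffer marker was at 9.17% of the Kupffer cell-like level (Clec4f at 0.387%), and in recognised ConA cells at 77.1% of the naive level. Either sum gave a log2 value within 1 SE of 0, so the sums cannot tell Kupffer cells that lost their markers from monocytes or dendritic cells. Counting all of cluster 15 as Kupffer cells leaves 895 naive and 12 ConA cells as monocyte or dendritic cell-like. At Leiden resolution 2, cluster 21, led by Ccl17 and Cd209a, was named monocyte or dendritic cell-like. Before doublet removal it held 20, 39, 92 and 51 ConA cells. Cluster 30 there, led by Lyz2 and Il1b, carried markers of both types and held 26, 86, 206 and 78. A candidate explanation that also stays open is another yield of Kupffer cells on dissociation after ConA, beside their loss, and the tables hold no count of cells in the tissue.

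Other results differed between genotypes or came from cells outside the classes. The interaction of genotype and ConA for Rpl36-ps3 in B cell-like cells was log2 -2.07. By camera with the preset correlation, 16 lists had an interaction, 7 to 35 with 1 library left out, and with an estimated correlation 0 (lowest adjusted p = 1). Cluster 25 held 125 analysed cells of ConA libraries and 0 of naive libraries, was led by Ccl4, Ccl1, Xcl1 and Ifng, and 67.9% of its cells before removal were called doublets. Cluster 27, led by Ccl21a, with Selp, Vcam1 and Sele among its leading genes, held 365 cells of ConA libraries and 0 of naive libraries. Cluster 34, led by Slpi and Igfbp6, held 196 cells of ConA and 80 cells of naive libraries.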

How the results depend on the processing

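The tests with a sex term, with cells of at least 1300 UMIs, with a minimum relative to the library median, with cluster 15 counted as Kupffer cell-like and without both ConA libraries rich in cluster 8 (replicate 1 of each ConA group) were chosen after the data were examined. Over 193 named gene results, 3122 of 3260 alternative values kept their direction and side of the threshold, 121 no longer passed, 14 newly passed and 3 reversed. Of the counts, 625 stayed within 1.5 times the value given and 180 moved. The ConA responses of Ccl2 and Icam1 in endothelial cell-like, Il1b and Tnf in Kupffer cell-like and Ifng in T cell-like cells kept their calls in every alternative run. Most often lost, in 9 alternatives each, were Csf2 in T cell-like cells, Elovl3 and Mup7. Leaving out a library gave fewer calls in some fits and more in others, and the cause was not tested.

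With the sex term the genes called for ConA against naive were 4310 in the whole library, 3170 in endothelial cell-like, 758 in erythroid cell-like, 455 in NK cell or ILC1-like and 214 in stellate cell or fibroblast-like cells. The genotype counts were 2 in B cell-like cells after ConA, and in naive mice 29 in monocyte or dendritic cell-like, 1 in NK cell or ILC1-like, 0 in plasmacytoid dendritic cell-like and 5 in T cell-like cells. The interaction gave 1 in T cell-like cells. With DESeq2 the ConA counts were 1770 in B cell-like, 638 in erythroid cell-like, 905 in Kupffer cell-like and 263 in NK cell or ILC1-like cells. Its genotype counts after ConA were 1 in the whole library and 0 in B cell-like and T cell-like cells, and in naive mice 0 in monocyte or dendritic cell-like, 1 in NK cell or ILC1-like and 0 in plasmacytoid dendritic cell-like cells. Its interaction counts were 0 in B cell-like and 1 in NK cell or ILC1-like cells. With at least 1300 UMIs the ConA counts were 1857 in B cell-like and 2644 in T cell-like cells, and 9 classes changed in share. No genes were then called for genotype after ConA in B cell-like or T cell-like cells (0 each) or in naive monocyte or dendritic cell-like and plasmacytoid dendritic cell-like cells (0 each). The direction reversed in endothelial cell-like cells for Mki67 (-0.08), Ube2c (-0.273) and Cdk1 (-0.123).

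With no low-count filter, which tests more genes with few UMIs, the ConA counts were 605 in hepatocyte-like and 866 in stellate cell or fibroblast-like cells. The naive genotype counts were 11 in B cell-like, 1 in cholangiocyte-like, 3 in endothelial cell-like, 3 in Kupffer cell-like, 10 in monocyte or dendritic cell-like, 6 in plasmacytoid dendritic cell-like, 12 in stellate cell or fibroblast-like and 12 in T cell-like cells. After ConA they were 15 in B cell-like cells, 17 in cluster 15, 150 in endothelial cell-like, 3 in erythroid cell-like, 1 in hepatocyte-like, 3 in Kupffer cell-like, 6 in neutrophil-like, 1 in NK cell or ILC1-like, 30 in stellate cell or fibroblast-like and 33 in T cell-like cells. The interaction counts were 19 in B cell-like, 40 in endothelial cell-like, 7 in hepatocyte-like, 2 in Kupffer cell-like, 1 in NK cell or ILC1-like, 3 in stellate cell or fibroblast-like and 27 in T cell-like cells. Without both ConA libraries rich in cluster 8 the naive genotype counts were 9 in B cell-like, 2 in cholangiocyte-like, 8 in erythroid cell-like, 8 in stellate cell or fibroblast-like and 13 in T cell-like cells. After ConA they were 0 in B cell-like cells, 4 in cluster 15, 2 in erythroid cell-like, 3 in Kupffer cell-like, 6 in stellate cell or fibroblast-like and 9 in T cell-like cells, and for the interaction 4 in B cell-like and 2 each in Kupffer cell-like, stellate cell or fibroblast-like and T cell-like cells. The strict cell filter gave 3 in B cell-like and 0 in T cell-like cells after ConA, and 1 in NK cell or ILC1-like and 6 in plasmacytoid dendritic cell-like cells of naive mice. Leiden resolution 2 gave 3 in B cell-like cells after ConA and 0 in naive monocyte or dendritic cell-like cells. With only the 4 libraries compared there were 8 in B cell-like cells after ConA, and 1 in stellate cell or fibroblast-like and 5 in T cell-like cells of naive mice. With an estimated correlation 0 lists were called in any of the 4 contrasts.

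With 1 library left out at a time, where a lone library is assumed to vary like the other groups, the naive genotype counts ranged from 0 to 3 in B cell-like, 0 to 6 in cholangiocyte-like, 0 to 1 in erythroid cell-like, 0 to 3 in Kupffer cell-like, 0 to 1 in NK cell or ILC1-like, 0 to 2 in stellate cell or fibroblast-like and 0 to 8 in T cell-like cells. They ranged from 1 to 67 in monocyte or dendritic cell-like cells (67 without villin-cre naive replicate 1) and from 2 to 22 in plasmacytoid dendritic cell-like cells. After ConA they ranged from 0 to 25 in B cell-like cells, 0 to 42 in cluster 15, 0 to 394 in endothelial cell-like (394 without villin-cre ConA replicate 2), 0 to 34 in erythroid cell-like, 0 to 5 in hepatocyte-like, 0 to 4 in Kupffer cell-like, 1 to 61 in neutrophil-like, 0 to 2 in NK cell or ILC1-like, 0 to 42 in stellate cell or fibroblast-like and 0 to 46 in T cell-like cells (46 without floxed ConA replicate 2). The interaction counts ranged from 0 to 17 in B cell-like, 0 to 27 in erythroid cell-like, 0 to 1 in Kupffer cell-like, 0 to 1 in NK cell or ILC1-like, 0 to 2 in stellate cell or fibroblast-like and 0 to 19 in T cell-like cells. The ConA counts ranged from 767 to 1546 in erythroid cell-like and from 165 to 278 in hepatocyte-like cells. The classes whose share differed by genotype in naive mice ranged from 0 to 1, and the lists called from 12 to 33 for genotype in naive mice and from 7 to 35 for the interaction.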

Other observations

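The comparisons in this part were chosen after the data were examined, except the marker sets and list tests; among the tests, that of Ifng-positive cells at equal depth was chosen after the result was seen. After ConA the cytokine genes came from different cells, given as mean CPM ± SD over 4 libraries. Neutrophil-like cells had the highest level of Il1b (6434 ± 1606), ahead of Kupffer cell-like cells (3694 ± 864) and cluster 15 (2376), and they also held Osm, the gene of oncostatin M (4407 ± 2383), Il6 (3116 ± 2148), Tnf (777 ± 86.7), Il4 (988 ± 490) and Il13 (381 ± 341). Of their 126 cells 8 had more UMIs of basophil than of neutrophil markers, and these held 77 of the 329 Il4, 320 of the 911 Il6, 265 of the 1212 Osm and 23 of the 119 Il13 UMIs. Basophil or mast cell markers were the next set of this class, with a score of 3.16 against 7.45. Villin-cre ConA replicate 2, with 0 such cells, held 14 Il4 and 35 Il6 UMIs. The other ConA libraries held 62 to 164 and 263 to 317. How much of these cytokines came from neutrophils is therefore not settled. Il6 was also found in Kupffer cell-like (788 ± 133, log2 8.23 ± 0.23 over naive) and stellate cell or fibroblast-like cells (364 ± 104, log2 7.56 ± 0.69). T cell-like cells held Il2, Il13 (477 ± 337) and Il4 (417 ± 328) besides Ifng. Lif had 308 UMIs in cholangiocyte-like, 302 in endothelial cell-like (16.1 CPM) and 112 in T cell-like cells of the ConA libraries (33.7 CPM, log2 6.83 ± 0.59). Il1a was at 1806.5 ± 423 CPM in Kupffer cell-like (log2 6.13 ± 0.30), 1118 ± 509 in neutrophil-like and 863 ± 203 in endothelial cell-like cells (log2 3.76 ± 0.19), which held most of its UMIs (17828 of 21831). Kupffer cell-like cells raised Il10, an anti-inflammatory cytokine gene, to 110 ± 32.9 CPM (log2 3.88 ± 0.32).

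At Leiden resolution 1 several classes changed cluster with ConA, while all NK cell or ILC1-like cells lay in cluster 10 in both. At resolution 2 this class parted too. Its cluster 18 there held 157, 157, 190 and 156 cells of the naive and 3, 8, 7 and 7 of the ConA libraries. Its other cluster held 1, 3, 1 and 8 cells of the naive and 67, 125, 114 and 137 of the ConA libraries. The clusters below are those of resolution 1. Endothelial cell-like cells lay in clusters 0 (78.6%) and 3 (14.3%) in naive mice and in 1 (72.1%), 8 (18.1%) and 28 (4.85%) after ConA. B cell-like cells moved from cluster 2 (98.7% of naive cells) to 7 (93.0% of ConA cells), Kupffer cell-like cells from 6 (99.7%) to 36 (94.1%), hepatocyte-like cells from 9 (67.3%) to 16 (87.6%) and erythroid cell-like cells from 14 (54.3%) and 26 (31.3%) to 32 (81.0%). After erythroid markers, B cell markers scored highest in cluster 26 (2.837) and T cell markers in cluster 39 (2.246, 13.9% of naive cells). Endothelial markers did so in clusters 32 (2.29) and 14 (1.863). The change of erythroid cell-like clusters thus includes a change in the other types' markers they carried. Before doublet removal hepatocyte-like cluster 9 held 361 and 736 cells of the male and 79 and 8 of the female naive libraries. Cluster 16 held 6 and 16 cells of the male and 159 and 100 of the female naive libraries. All ConA mice were female, so the change of hepatocyte-like clusters cannot be told apart from sex. T cell-like cells of naive mice lay mainly in clusters 4 and 5 and those of ConA mice in clusters 11 (77.6%) and 35 (20.3%). In cluster 35 Ifng was at 5731 and 5015 CPM in floxed and 4026 and 7195 CPM in villin-cre ConA libraries, against 250 and 243 and then 1677 and 867 CPM in cluster 11. Endothelial cell-like cluster 8, led by Ccl2, Cxcl10 and Ch25h, took 12.7% (Wilson 95% interval 11.2 to 14.4) and 2.05% (1.65 to 2.55) of the cells of the floxed ConA libraries. In the villin-cre ConA libraries it took 26.7% (25.3 to 28.2) and 0.932% (0.693 to 1.25). With cells thinned to 1000 UMIs each, 19.5% (16.1 to 23.5) and 22.1% (18.5 to 26.0) of T cell-like cells held an Ifng UMI in the villin-cre ConA libraries. In the floxed ConA libraries 13.3% (8.86 to 19.5) and 12.8% (9.69 to 16.7) did. In naive libraries 7.38% (4.17 to 12.7) and 3.66% (2.15 to 6.16) did in villin-cre and 2.46% (1.38 to 4.34) and 3.27% (1.40 to 7.42) in floxed mice. Cells under 1000 UMIs were left out. These were 851 of 1000 and 223 of 578 T cell-like cells in villin-cre naive libraries. They were 506 of 954 and 531 of 684 in floxed naive libraries, and 0 in each ConA library. Over all cells without thinning, the naive shares were 3.5 and 4.84% in villin-cre and 2.83 and 2.78% in floxed mice. Of NK cell or ILC1-like cells 41.2% (32.7 to 50.2) and 54.5% (46.4 to 62.5) did in the villin-cre and 41.4% (30.6 to 53.1) and 47.7% (39.3 to 56.2) in the floxed ConA libraries. Of B cell-like cells, which should lack the gene, 0.105% and 0.293% did on average. Mean of the median depths before thinning was 2190 UMIs in villin-cre and 2312 in floxed libraries for T cell-like and 1559 and 1626 for B cell-like cells.

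Marker sets in the whole library, ConA against naive, gave the following numbers of genes higher and lower. Neutrophil markers had 6 higher and 0 lower of 10 (median log2 3.42), platelet markers 5 and 0 of 5 (2.76), and stellate markers 7 and 0 of 9 (1.52). Cholangiocyte markers had 4 and 0 of 7 (1.07), NK markers 4 and 1 of 10 (0.53), basophil markers 1 and 0 of 5 (0.50) and endothelial markers 1 and 0 of 11 (0.05). Kupffer markers had 0 and 10 of 10 (-1.45), plasmacytoid dendritic markers 1 and 5 of 8 (-1.27), erythroid markers 0 and 2 of 6 (-1.10), and plasma cell markers 1 and 2 of 7 (-1.03). T cell markers had 0 and 7 of 8 (-0.97), B cell markers 0 and 5 of 7 (-0.75), hepatocyte markers 1 and 2 of 9 (-0.54), monocyte markers 1 and 4 of 10 (-0.42) and conventional dendritic markers 2 and 3 of 10 (-0.31). Within the classes, called markers of other cell types went higher and lower in these numbers: 19 and 16 in endothelial cell-like, 12 and 18 in erythroid cell-like, 6 and 20 in B cell-like, 6 and 13 in T cell-like, 1 and 6 in NK cell or ILC1-like and 1 and 5 in hepatocyte-like cells.

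The ConA response of floxed and villin-cre mice was alike across genes, which are not independent replicates. Of 9 such correlations, Pearson's r was 0.90 in the whole library (Spearman's rho 0.88, 13857 genes), 0.90 in endothelial cell-like (0.85), 0.89 in T cell-like (0.90) and 0.84 in B cell-like cells (0.82). It was 0.86 in Kupffer cell-like (0.75), 0.86 in erythroid cell-like (0.76), 0.78 in NK cell or ILC1-like (0.68), 0.77 in hepatocyte-like (0.51) and 0.67 in stellate cell or fibroblast-like cells (0.53). Of the genes called in both genotypes, 2844 of 2844 in the whole library and 2697 of 2700 in T cell-like cells moved in the same direction. In the whole library 3269 genes were called in floxed and 4493 in villin-cre mice, and in T cell-like cells 3230 and 3695. Both genotypes shared the differences in sex, mouse series and depth between naive and ConA libraries, so the likeness need not come from ConA alone.

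Remaining list results after ConA were as follows. Immediate-early genes had 13 higher and 2 lower of 20 in the whole library, 15 and 2 adjusted over the list alone (median 1.48, camera adjusted p = 7.17e-05; adjusted p = 0.471 with an estimated correlation). Cell death genes had 10 and 1 of 17 (median 0.70, camera adjusted p = 0.0056; adjusted p = 0.172 with an estimated correlation), heat shock genes 6 and 0 of 9 (median 1.02, camera adjusted p = 0.0314; adjusted p = 0.541 with an estimated correlation) and acute phase genes 6 and 0 of 16 (median 0.82, camera adjusted p = 0.00667; adjusted p = 0.454 with an estimated correlation). Effector genes in B cell-like cells had a median of 0.80 and a mean of 0.53, while camera put the list down relative to other genes (adjusted p = 0.977). Of 11 endosomal TLR genes in endothelial cell-like cells 5 rose (median 0.33, camera adjusted p = 0.0145; adjusted p = 0.195 with an estimated correlation).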
